A study of Rattus norvegicus with 25 samples.

How the data were processed

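Total RNA was extracted with a column kit and made into stranded, rRNA-depleted libraries, per the labels' protocols. STAR alignment to rat build rn6 after FastQC is named in the submitters' processing notes; the counting tool, annotation release, strand setting and treatment of multi-mapping reads are not given in the sources used here. The deposited table holds whole-number counts for 32883 Ensembl rat gene IDs in 25 libraries, not normalized by the authors, per the values themselves and the labels. IDs that share reads with a near copy cannot be told apart without the counting rule, so each ID below stands for what the authors counted on it. The cell line comparison named in the design text is not analysed here.

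None of the 32883 IDs could be given a symbol: the files do not pair the IDs with names, and 0 lines of the reference gene table carry one of these IDs. The gene lists and the name-based rule fixed before the data were examined therefore could not be applied. At most 2 risen and 2 fallen IDs are printed per comparison, by the rest of that rule: adjusted p under 0.05, a mean of at least 5 CPM over the compared samples, no overlap between the groups, and the largest absolute log2 change. Exceptions are said where they occur.

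Groups came from the sample titles. The number after OLE was read as the rat, and the 2 libraries of rat 13 within a group were summed, so that each rat counted once per group (4, 4 and 3 samples). Each RYGB number still entered the unblocked OLE fit with both kinds of section, and that fit treated them as independent samples. Those libraries were not one library deposited again: the chi-square per degree of freedom over IDs with at least 20 counts was 35.6 between both Glucotonic_OLE 13 libraries, and the lowest between any libraries of a group was 16.3. Whether first-cohort limbs with one number came from one rat is not stated. The labels describe no further replicate structure, so p-values measure the spread between these samples.

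Each cohort was fitted on its own with edgeR 4.0.16 (R 4.3.3): filterByExpr by group (at least 10 counts in enough libraries and 15 in total), TMM scaling, a robust quasi-likelihood fit with a common spread over the cohort's groups, and Benjamini-Hochberg adjustment with a threshold of 0.05. CPM are computed here on TMM-scaled libraries. SEs are the log2 change divided by the root of the F statistic. The biological coefficient of variation was 0.314 in the first cohort and 0.279 in the OLE cohort. Alternatives set before the data were examined were DESeq2 1.42.0 (Wald test), its size factors in the edgeR test, no low-count filter, fits of only the groups compared, each replicate left out, libraries of rat 13 kept apart, lane 7 as a covariate, lane 7 only, without lane 7, and the rat number as a block. Overlaps of calls used Fisher's exact test with two-sided p.

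The OLE numbers were taken to pair the sections. Deviations from the group mean (log2 CPM with a prior count of 2) correlated between sections of one number at r = 0.467 (13), 0.43 (16), 0.341 (18) and 0.811 (19), all above 0.1. The highest r with a section of another number was 0.412 (13), 0.221 (16), 0.444 (18) and -0.275 (19). Numbers 13, 16 and 18 thus also passed 0.1 against other numbers, so this check sets only number 19 apart and does not establish the pairing of the others. The design text places both kinds of section in rats after RYGB without saying that a number is 1 rat; the blocked result is given beside the unblocked one.

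IDs called in the alimentary limb, and IDs called between sham ileum and sham jejunum, were used as groups after the data were seen. Their shifts were tested with camera in limma 3.58.1 (preset correlation 0.01, with an estimated correlation and fry, which sets a group against no change and not against other IDs, as alternatives), adjusted over 12 tests in the OLE cohort and 2 in the common limb. A limb score is the mean log2 CPM of the alimentary-risen IDs minus that of the fallen IDs, relative to the mean of the Sham_OLE libraries. The segment index is the mean log2 CPM of up to 200 ileum-high IDs minus that of 200 jejunum-high IDs. These were chosen 3 times with 1 sham number held out each time. In each round it is scaled to 0 at the mean of the Sham_JEJU libraries not held out and to 1 at that of Sham_IL. A sham library takes the value from the round without its number, and other libraries the mean of the rounds. For the limb score and the segment index, the libraries of both cohorts were TMM-scaled together. A difference between cohorts in the segment IDs would therefore shift the index of the OLE libraries. Intervals and floors of 3 counts cover counting error only.

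Total counts were examined per library, not summed, when samples far from their group were looked for. The gene test was tested on simulated counts with 200 changed IDs per comparison, 100 by 2-fold and 100 by 4-fold. It recovered 15% and 65% of them for RYGB_AL against Sham_JEJU (15800 IDs), 27% and 67% for RYGB_CL against Sham_IL, 40% and 71% for Glucotonic_OLE against Sham_OLE (14418 IDs), 42% and 89% for Glucotonic_OLE against Nonglucotonic_OLE, 30% and 74% for Nonglucotonic_OLE against Sham_OLE, and 2% and 41% for the difference between limbs. Between 0% and 7.84% of the calls in these simulations were unchanged IDs. A single set was simulated per comparison, with IDs drawn independently and without lane or rat structure. Differences between comparisons may be noise of the draw, and these rates do not cover such structure in the real samples.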

Results

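RNA from rat small intestine was sequenced after Roux-en-Y gastric bypass (RYGB), an operation that joins a small stomach pouch to the mid-jejunum, or after sham surgery. A first cohort gave 12 libraries in 4 groups of 3: the alimentary limb (RYGB_AL), which carries food from the pouch, the common limb (RYGB_CL), in which food meets bile and pancreatic juice, and the jejunum (Sham_JEJU) and ileum (Sham_IL) of sham rats. An OLE cohort of 13 libraries came from OLETF rats, a strain that becomes obese and diabetic. It held intestinal sections that the submitters called glucotonic (Glucotonic_OLE, 5 libraries of 4 rat numbers) or non-glucotonic (Nonglucotonic_OLE, 5 libraries of 4 rat numbers) after RYGB, and sham distal intestine (Sham_OLE, 3 rat numbers). Sequencing lanes 4 to 7 were named for the OLE libraries, and all 3 Sham_OLE libraries came from lane 7.

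Total counts per library, in M for the SI prefix mega, were 23.7 to 49.3 M in the first cohort and 18.1 to 25.6 M in the OLE cohort. A pair of IDs took much of the OLE libraries: ENSRNOG00000043866 held 35.5% to 52.6% of each library's counts there, against at most 1.47% in the first cohort, and ENSRNOG00000030478 held 3.88% to 15.7%. The counts left for all other IDs in the OLE cohort were 8.48 to 12.8 M per library, so low IDs were read less precisely there than in the first cohort.

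**Figure D1:**
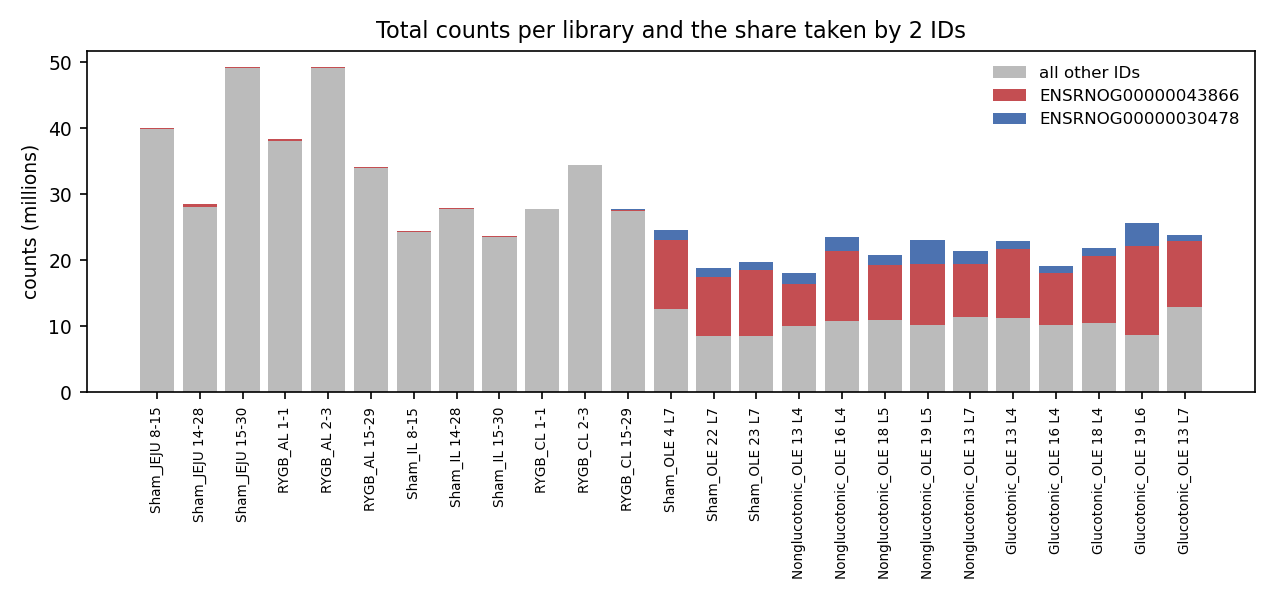
Total counts per library in M, split into 2 abundant IDs and all others; L with a number is the lane. All 13 OLE libraries carry the large red share of ENSRNOG00000043866, which is thin in the 12 libraries of the first cohort.

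The alimentary limb was compared with sham jejunum to ask what surgery changed in the segment that receives undigested food. It differed widely: of 16146 IDs tested, 719 were higher in RYGB_AL and 518 were lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median log2 change was 1.44 among the risen and -1.15 among the fallen IDs, and 236 risen against 82 fallen IDs changed more than 4-fold. These medians were the same, and so were the counts past 4-fold, when the 5 risen IDs without a count in any Sham_JEJU library were set at their lower bound of 3 counts over that group.

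Among the risen IDs, ENSRNOG00000032626 went from 0.0165 ± 0.0285 CPM in Sham_JEJU to 23.5 ± 16.8 CPM in RYGB_AL (mean ± SD, n = 3 each). Its Sham_JEJU libraries held 2 counts together, a ratio of 1300 with a 95% counting interval of 360 to 10800 (adjusted p = 0.00112, edgeR). ENSRNOG00000002792 reached 11.8 ± 15.8 CPM in RYGB_AL, from 0.77 in library 1-1 to 29.9 in library 2-3, against 3 counts in Sham_JEJU (ratio 465, interval 159 to 2260, adjusted p = 0.00664, edgeR). Of the fallen IDs, ENSRNOG00000028616 dropped from 468.5 ± 280 CPM to 4.94 ± 2.93 CPM (log2 change -6.56, SE 0.70, adjusted p = 0.000553, edgeR). ENSRNOG00000051171 was at 22.7 ± 9.43 CPM in Sham_JEJU and 0.0598 ± 0.0781 CPM in RYGB_AL (log2 change -8.55, SE 0.73, adjusted p = 0.000189, edgeR). The number of changed IDs was 484 without RYGB_AL library 15-29, 503 without RYGB_AL 2-3, 557 without Sham_JEJU 14-28 and 792 without Sham_JEJU 8-15. DESeq2 called 1968 IDs in the same libraries.

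For the common limb against sham ileum, the question was whether the segment beyond the junction changed as well. No ID passed the threshold among 16146 tested with edgeR, where the lowest adjusted p was 0.0778; 1268 IDs had an unadjusted p under 0.05, and DESeq2 called 93 (61 higher and 32 lower). Without RYGB_CL library 2-3, edgeR called 56 IDs, 40 of them higher. The IDs that rose in the alimentary limb leaned the same way here: 538 of the 719 (74.8%) were higher in RYGB_CL than in Sham_IL, against 54.5% of the remaining IDs, and 162 of the 518 fallen IDs (31.3%) were higher. That group shift passed camera with a preset correlation (adjusted p = 3.35e-07 for the risen and 9.9e-10 for the fallen IDs) but not with an estimated one (adjusted p = 0.114 for each). The same numbers occur in both limbs and whether they mark the same rats is not stated, so these shifts are not taken as independent of the alimentary limb values.

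The surgery effect itself differed between limbs for 98 IDs by the interaction test (edgeR, adjusted p under 0.05). For 82 of them the alimentary effect was the higher one, with a median log2 change of 2.29 in the alimentary limb and 0.0488 in the common limb. For the other 16 the medians were -1.97 and 0.0722. Of these 98 IDs, 81 and 15 had also passed the test for the alimentary limb, in the respective directions, from the same libraries. Single libraries moved this count from 8 (without Sham_IL 8-15) to 127 (without RYGB_CL 2-3), with 12 without RYGB_AL 15-29, 12 without Sham_IL 15-30, 15 without Sham_JEJU 14-28, 19 without RYGB_AL 2-3, 36 without Sham_IL 14-28, 45 without RYGB_CL 1-1, 46 without Sham_JEJU 15-30 and 50 without Sham_JEJU 8-15.

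**Figure D2:**
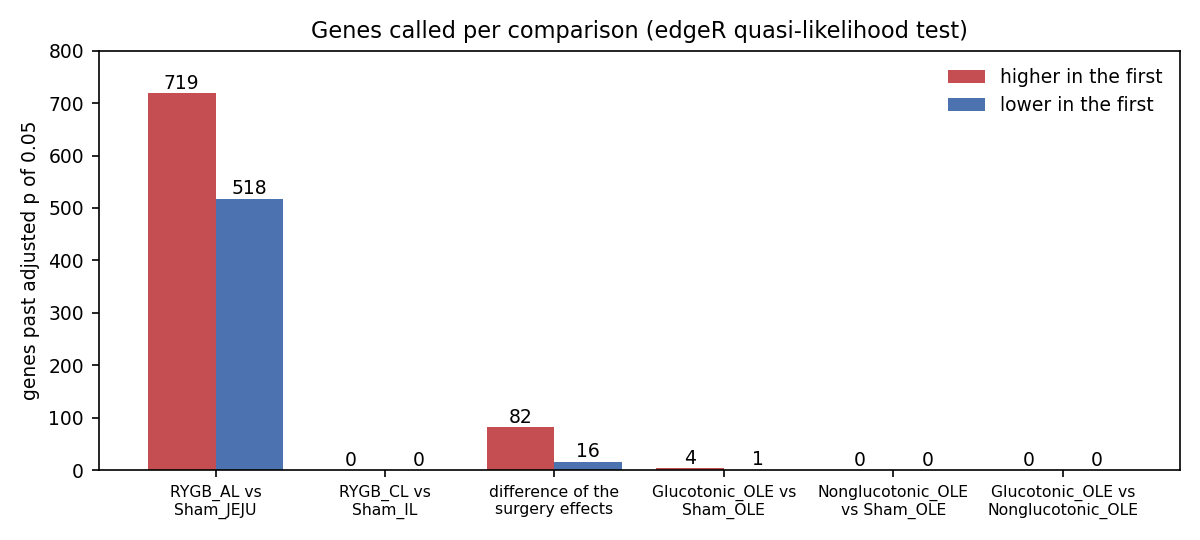
Number of IDs past an adjusted p of 0.05 (edgeR quasi-likelihood test) in each comparison, higher (red) or lower (blue) in the first-named group. RYGB_AL against Sham_JEJU has 719 and 518, the difference between the limbs' surgery effects 82 and 16, and the OLE comparisons at most 4 and 1.

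In OLETF rats, glucotonic sections were compared with sham distal intestine. Of 14495 IDs tested, 4 were higher and 1 was lower in Glucotonic_OLE (edgeR, adjusted p under 0.05). ENSRNOG00000021824 stood at 109 ± 18.5 CPM (n = 4) against 31.9 ± 4.54 CPM in Sham_OLE (n = 3), a log2 change of 1.77 with an SE of 0.25 (adjusted p = 0.0459, edgeR). The same ID had risen in the alimentary limb by 2.12 on the log2 scale (SE 0.25, adjusted p = 0.000672, edgeR), where the 3 RYGB_AL libraries held 287 to 458 CPM and the 3 Sham_JEJU libraries 68 to 116 CPM. ENSRNOG00000037690 was at 7.97 ± 0.835 CPM against 3.26 ± 0.597 CPM, and ENSRNOG00000018960 fell from 155 ± 26.1 CPM to 78.5 ± 2.66 CPM (adjusted p = 0.0459 for both, edgeR).

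**Figure D3:**
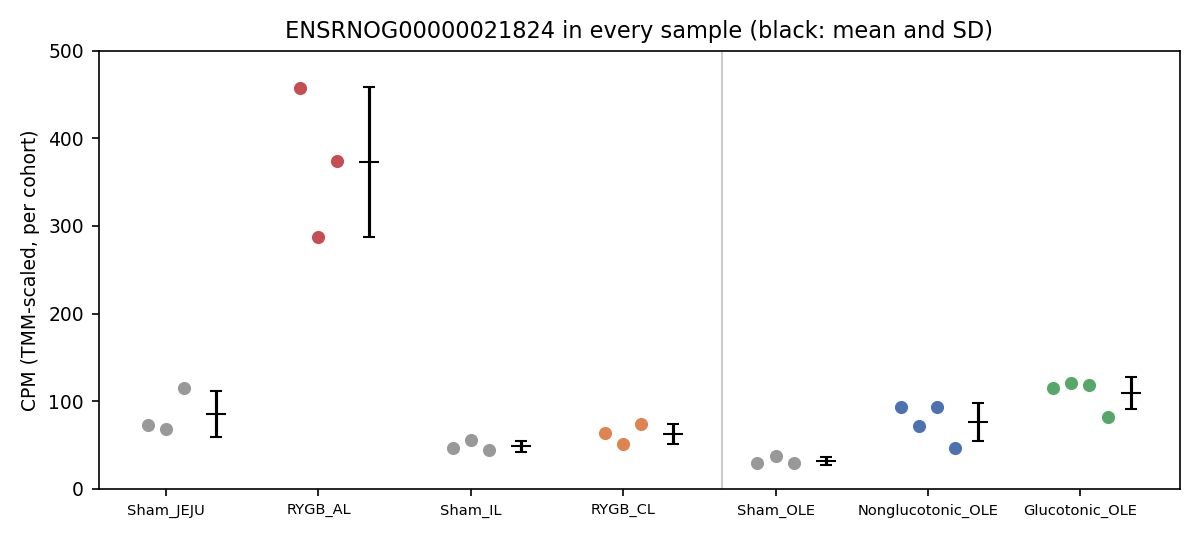
ENSRNOG00000021824 in CPM (TMM-scaled within each cohort) for every sample, with the mean and SD of each group in black. The RYGB_AL libraries lie at 287 to 458 CPM, above the Sham_JEJU libraries, and the Glucotonic_OLE samples (81.6 to 121 CPM) lie above the Sham_OLE samples (29 to 37.2 CPM).

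This count rested on few samples. With both sections of number 19 left out, a choice made after the data were seen, edgeR called 1862 IDs (937 higher and 925 lower in Glucotonic_OLE), with a biological coefficient of variation of 0.213 in place of 0.279. With the libraries of number 13 also kept apart, and so counted as separate samples, it called 2378, and 39 once lane 7 was added to that fit as a covariate. Of single samples left out of the full set, Sham_OLE 4 gave 103 calls, and there were 8 without Glucotonic_OLE 19, 2 without Sham_OLE 22 and 0 without Glucotonic_OLE 13, 16 or 18 or without Sham_OLE 23. DESeq2 called 485 of the full set. The spread of the full edgeR fit also draws on the non-glucotonic sections of the same numbers. Fitted with only the groups compared, edgeR called 0 IDs. The adjusted p was then 0.051 for ENSRNOG00000021824, 0.12 for ENSRNOG00000037690 and 0.134 for ENSRNOG00000018960 (edgeR). With lane 7 as a covariate, which rests on the number 13 libraries, edgeR called 0 IDs, against 31 with libraries kept apart and no lane term and 5 with them summed (2380 at an unadjusted p under 0.05). The log2 change of ENSRNOG00000021824 was 1.70 (SE 0.35) with the lane term and 1.81 (SE 0.29) without it in the separate libraries, that of ENSRNOG00000037690 0.97 (SE 0.22) against 1.32 (SE 0.20), and that of ENSRNOG00000018960 -0.80 (SE 0.17) against -0.96 (SE 0.13), with an adjusted p of 0.44 for each with the lane term (edgeR). Over 19 alternatives the adjusted p of these IDs ran from 1.35e-27 (DESeq2 without number 19) to 0.891 (edgeR, lane 7 only, where 1 glucotonic library stood against 3 of sham and the test says little).

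Sham_OLE 4 differed from the other sham samples in the IDs that separate sham jejunum from sham ileum. On an index of such IDs, scaled to 0 at Sham_JEJU and 1 at Sham_IL, it lay at 0.146, while Sham_OLE 22 and 23 lay at 0.716 and 0.917. The scale comes from the first cohort, so a difference between cohorts in these IDs would move the OLE values. Glucotonic_OLE had a mean index of 0.740 ± 0.0745 (SD, n = 4) and Nonglucotonic_OLE one of 0.680 ± 0.115 (SD, n = 4).

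**Figure D4:**
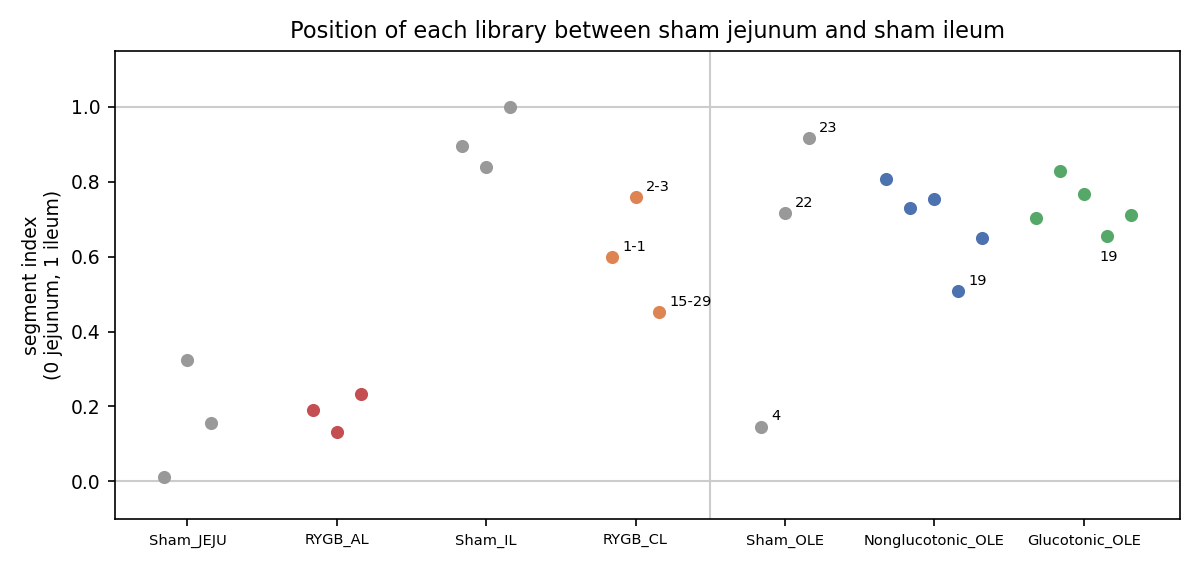
Segment index of each library, from IDs that differ between sham jejunum (0) and sham ileum (1), with the values of each sham library taken from IDs chosen without its own number. Sham_OLE 4 lies at 0.146, nearest to 0 of the OLE libraries, and the RYGB_CL libraries lie between 0.451 and 0.759.

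Non-glucotonic sections were set against the same Sham_OLE samples. No ID passed the threshold (edgeR, 14495 tested, lowest adjusted p 0.28), 936 had an unadjusted p under 0.05, and DESeq2 called 26. ENSRNOG00000021824 averaged 1.26 higher on the log2 scale than in Sham_OLE (adjusted p = 0.365, edgeR). Leaving out both sections of number 19 raised the edgeR count to 157 (91 higher and 66 lower), and to 302 with the libraries of number 13 also kept apart, but adding lane 7 as a covariate to that fit left 1. From the full set, without Sham_OLE 4 it was 3, and without Nonglucotonic_OLE 19 it was 1.

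Glucotonic and non-glucotonic sections, which carry the same 4 rat numbers, address what sets a glucotonic section apart after RYGB. Without the number as a term, no ID passed (edgeR, 14495 tested); 388 had an unadjusted p under 0.05, and DESeq2 called 3. With the number as a block, 25 of 14004 IDs passed, 10 higher with a median log2 change of 0.82 and 15 lower with a median of -1.55, and 1800 had an unadjusted p under 0.05. ENSRNOG00000010708 had the most negative log2 change of these, -5.22 (SE 0.29, adjusted p = 2e-04, edgeR with the block), and ENSRNOG00000003977 the most positive, 1.41 (SE 0.15, adjusted p = 0.0158, edgeR with the block). Both IDs were picked after their values were seen, by log2 change alone. The rules of 5 CPM and of no overlap between the groups were not applied to them, so low counts are not excluded. Neither passed without the block. The blocked count was 6 without number 19, 9 without 16, 15 without 18 and 223 without 13, whose sections came as 2 libraries each. By edgeR it was 0 with the libraries of number 13 kept apart and 1 with lane 7 as a covariate in that fit. The count of 25 therefore changed with each number left out and with how number 13 entered the fit. The cause was not tested.

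Calls were compared across the cohorts, which share no libraries. Of the 4 IDs higher in Glucotonic_OLE than in Sham_OLE, 1, ENSRNOG00000021824, was among the 654 alimentary-risen IDs tested in both, where independent lists would share 0.183 (Fisher's exact test, two-sided, p = 0.171). At an unadjusted p under 0.01 in both comparisons, 94 IDs were higher in RYGB_AL and in Glucotonic_OLE, where independent lists of 917 and 370 IDs would share 23.7 (Fisher's exact test over IDs, which are not independent replicates, two-sided, p = 2.58e-32, adjusted p = 3.1e-31 over 12 tests), and 50 were lower in both against 21.8 (p = 3.48e-08, adjusted p = 8.35e-08, same exact test). Without number 19, the IDs called by edgeR in both were 99 higher, against 42.6 for independent lists, and 35 lower, against 32.6 (Fisher's exact test, two-sided, p = 1.65e-15 and 0.644). Without the number as a block, the alimentary limb and the contrast of glucotonic with non-glucotonic sections shared 26 higher IDs at an unadjusted p under 0.01, against 3.2 for independent lists, and 6 lower IDs against 1.08 (Fisher's exact test, two-sided, p = 1.83e-18 and 5e-04, adjusted p = 1.1e-17 and 0.000857). At an adjusted p under 0.05 this pair shared 0 IDs by edgeR, which called none in the second contrast (388 at an unadjusted p under 0.05), and by DESeq2 1 higher ID, against 0.187 (Fisher's exact test, two-sided, p = 0.176), and 0 lower. With the block, 3 of the 10 IDs called higher were alimentary-risen and 1 of the 15 called lower was alimentary-fallen, which was not tested against chance. Non-glucotonic sections against sham shared 13 higher IDs with the alimentary limb at an unadjusted p under 0.01, against 4.1 for independent lists, and 14 lower IDs against 6.56 (Fisher's exact test, two-sided, adjusted p = 0.000346 and 0.0105). At this threshold the sharing was therefore not limited to glucotonic sections, but both contrasts use the same Sham_OLE samples. DESeq2 calls shared 6 higher IDs, against 0.866, and 1 lower ID, against 0.658. As a group, alimentary-risen IDs were shifted by only 0.0426 in non-glucotonic sections against sham (camera adjusted p = 0.238). The fallen IDs were shifted the opposite way to the alimentary limb, by 0.0317 (camera adjusted p = 0.455). At the same unadjusted threshold, the common limb shared 10 higher IDs with Glucotonic_OLE, against 4.6 (Fisher's exact test, two-sided, p = 0.0266, adjusted p = 0.0355), and 3 lower IDs against 3.37. By DESeq2 calls this overlap was not past the threshold, with 3 higher IDs against 0.984 (Fisher's exact test, two-sided, p = 0.0751, adjusted p = 0.15) and 0 lower.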

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

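Tests of lane, segment position, depth and likeness to sham in this part were chosen after the results were seen; the counts over other splits of the samples were not. The surgery effect differed between the alimentary and the common limb for 98 IDs by the interaction test. The real split of the numbers gave 98 and the highest of the other splits 0, but 10 splits, of which 1 reached the real count, are too few for a share under 0.05. In Glucotonic_OLE, 2279 IDs of sample 19 lay more than 2-fold from the mean of the other samples, and the next sample had 564. ENSRNOG00000030478 took 13.3% of the counts of Glucotonic_OLE 19, against at most 5.94% in the others. ENSRNOG00000021824 was at 81.6 CPM in Glucotonic_OLE 19, against at least 116 CPM in the others. ENSRNOG00000018960 was at 74.5 CPM in Glucotonic_OLE 18, with 79.4 CPM as the next value. The segment index of Nonglucotonic_OLE 19 was 0.508, with 0.729 as the next value. Of 18 groups of values examined, 5 held such a sample. These groups reuse the same sections, and all flags but that of Glucotonic_OLE 18 fell on number 19. The rate of about 1 in 20 that chance flags among independent groups is therefore no yardstick here.

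Both sections of number 19 stood apart from those of the other RYGB numbers, in the same way (r = 0.811 between their deviations). A position nearer to jejunum or ileum as the whole cause is argued against by a rho of at most 0.181 in size (-0.181) between the deviations and the sham ileum minus jejunum difference across IDs, which are not independent replicates. On the segment index, however, both sections of number 19 were the lowest of their groups, at 0.656 (glucotonic) and 0.508 (non-glucotonic). A position nearer to jejunum as part of the cause is therefore not excluded. Lane stays open, since lane 6 held only Glucotonic_OLE 19 and lane 5 only 1 other section, Nonglucotonic_OLE 18; that section lay at a median of 0.168 (absolute log2 difference) from its group and Nonglucotonic_OLE 19 at 0.369, but 1 library gives no spread for a lane. The differences of both sections of number 19 from another number followed the sham minus RYGB difference of the remaining numbers with a rho of 0.467 to 0.58. Both differences are measured from numbers 13, 16 and 18, so a profile that only these numbers share would also give a positive rho. This rho is therefore no sign of likeness to sham. For numbers 13, 16 and 18 rho ran from -0.276 to 0.276. That range is symmetric by construction, since exchanging a number with its baseline flips the sign. It also rests on fewer remaining numbers, so it is no reference spread for number 19. A weaker response to surgery was not shown by the values at hand. Glucotonic_OLE 19 had the highest limb score (0.608), and Nonglucotonic_OLE 19 the highest of its group by number (0.127). Glucotonic_OLE 19 lay at a root mean square log2 difference of 0.706 to 0.909 from the sham libraries. The other glucotonic libraries lay at 0.639 to 0.85. Nonglucotonic_OLE 19 lay at 0.611 to 0.753, within the 0.58 to 0.788 of the other non-glucotonic libraries. Each section of number 19 is 1 library, so a weaker response stays open. Wrong labels, health and cell makeup were not tested.

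Sham_OLE 4 stood apart from the other sham samples: its deviations across IDs had a rho of -0.639 with the sham ileum minus jejunum difference, below every RYGB OLE section. Sham_OLE 23 deviated the other way (rho 0.691), and with each sample set against the mean of the other 2 these values are not independent. Taken in pairs, the difference of sample 4 from 22 and from 23 had a rho of -0.505 and -0.714 with that segment difference, and that of 22 from 23 one of -0.36, so the 3 sham samples were spread along it, with sample 4 at the jejunum end. Depth as the whole cause is argued against: without the 2 abundant IDs and with its counts thinned at random to the 8.46 M, over tested IDs, of the shallowest sham sample, sample 4 kept a rho of -0.633 to -0.628 over 20 draws. The tissue may have been taken nearer to the jejunum than in the other rats, a position that no label gives; a wrong sample label would look the same.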

How the results depend on the processing

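Alternatives that leave out number 19, 13, 16 or 18 whole, remove the 2 abundant IDs or join the block with libraries kept apart without a lane term, and all tests of gene groups and sham segments, were chosen after the results were seen. DESeq2 called 1968 IDs in RYGB_AL against Sham_JEJU, 93 in RYGB_CL against Sham_IL, 485 in Glucotonic_OLE against Sham_OLE, 3 in Glucotonic_OLE against Nonglucotonic_OLE, 26 in Nonglucotonic_OLE against Sham_OLE, 532 for the difference between limbs and 2520 between sham segments. Without a low-count filter edgeR called 1 ID in the common limb and 28 in Glucotonic_OLE against Sham_OLE. That last count was 0 with only the groups compared, 31 with libraries kept apart, 0 with lane 7 as a covariate in that fit, 0 with lane 7 only (an arm of 1 library, so this says little), 1 without the 2 abundant IDs, and 1862 without number 19 (2378 with libraries kept apart, 39 with the lane covariate in that fit, 2504 by DESeq2). Non-glucotonic sections against sham gave 157 IDs without number 19, 302 with libraries also kept apart, 1 with the lane covariate in that fit and 825 by DESeq2. Leaving out single replicates gave 484 to 1212 IDs for the alimentary limb, 0 to 56 for the common limb, 8 to 127 for the difference between limbs, 0 to 103 for glucotonic and 0 to 3 for non-glucotonic sections against sham, 0 to 1 between both kinds of section, and 235 to 1580 between sham segments. Where this left 2 samples in a group, the spread was shared with the other groups. The cause of these changes was not tested.

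With the replicate block, glucotonic against non-glucotonic sections gave 25 IDs, 0 with libraries kept apart, 1 with the lane covariate in that fit, and 223, 9, 15 and 6 without number 13, 16, 18 and 19; without the block, leaving out 13 gave 2. For the difference between limbs the block gave 69 IDs. The first-cohort numbers were not taken to pair the samples: no label says that they mark rats, and same-numbered deviations correlated at -0.0481, 0.275 and 0.166 between RYGB limbs and at 0.0295, 0.0636 and 0.0869 between sham segments.

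At an unadjusted p under 0.01, the alimentary limb shared 94 higher and 50 lower IDs with glucotonic against sham, 26 and 6 with glucotonic against non-glucotonic, 13 and 14 with non-glucotonic against sham, and 36 and 35 with the common limb, which shared 10 higher IDs with glucotonic against sham. DESeq2 calls of the alimentary limb shared 78 and 31 with glucotonic against sham, 1 and 0 with glucotonic against non-glucotonic, 6 and 1 with non-glucotonic against sham, and 16 and 12 with the common limb, which shared 3 and 0 with glucotonic against sham; the 1 and 0, the 1 lower and the 3 and 0 were not beyond chance (Fisher's exact test). Without number 19, 99 higher IDs were shared with glucotonic against sham. The shift of the alimentary-fallen IDs in glucotonic against sham, -0.101 from the other IDs, had p = 0.405 in camera with an estimated correlation (fry, against no change: p = 0.205); it was -0.0743 with libraries kept apart, 0.000411 with the lane covariate in that fit, -0.0076 without number 19, and -0.156 to 0.00746 over single replicates left out, the highest without Sham_OLE 4 and -0.00807 without Glucotonic_OLE 19. Against non-glucotonic sections their shift of -0.124 had p = 0.0738 with an estimated correlation (fry, against no change: p = 0.146); with the block it was -0.127 (p = 0.117 with an estimated correlation), and that of the risen IDs 0.163 (p = 0.0616). The risen IDs' shift against sham, 0.237, was 0.222 with libraries kept apart and 0.0967 with the lane covariate in that fit. The cause was not tested. Of 105 values of the comparisons under alternatives set beforehand, 52 stayed on their side and within 1.5 times; of 82 for single IDs, 57 did and 25 lost the threshold, with no change of sign. The gene list alternatives were not run, since no ID has a name. The number of counts outside the 2 abundant IDs, 8.48 to 12.8 M, limits the low IDs of the OLE cohort.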

Other observations

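The comparison of sham segments, the segment index, the limb score and the tests of gene groups, with the split counts of the shift within numbers and against sham, were chosen after the data were seen. Sham ileum and sham jejunum differed in 1489 of 16146 IDs (edgeR, adjusted p under 0.05), 444 higher in ileum and 1045 higher in jejunum; all 10 splits of the 6 samples are too few for a share under 0.05, the highest other split giving 0 and 1 split reaching the real count. ENSRNOG00000020899 was at 155 ± 103 CPM in Sham_IL (n = 3) and had 1 count in all of Sham_JEJU, a ratio of 16700 with a counting interval of 3000 to 660000. ENSRNOG00000058652 had the largest fall towards ileum (log2 change -11.14, adjusted p = 0.0405, edgeR), but this rested on Sham_JEJU 8-15, at 1127 CPM against 1.72 and 2.44 CPM in the other 2, and was -3.65 (adjusted p = 0.182) without it. ENSRNOG00000036959 was at 404 ± 416 CPM in Sham_JEJU and 0.231 ± 0.155 CPM in Sham_IL, and the common limb libraries 1-1 and 15-29 held 30.1 and 29.7 CPM of it, but library 2-3 held 0.228 CPM, at the Sham_IL level. The segment count was 235 without Sham_IL 15-30, 275 without Sham_IL 8-15, 546 without Sham_JEJU 8-15, 690 without Sham_JEJU 15-30 and 882 without Sham_IL 14-28.

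Common limb libraries lay between sham jejunum and sham ileum. Their segment index was 0.603 ± 0.154 (SD, n = 3), from 0.451 in library 15-29 to 0.759 in library 2-3, against 0.913 ± 0.0845 in Sham_IL (n = 3), and all 3 were below all 3 Sham_IL libraries (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 can give; adjusted p = 0.267 over 8 tests). With IDs chosen without the sham number they were compared with, 68.7% to 87.4% of ileum-high IDs were lower and 89.5% to 98.5% of jejunum-high IDs were higher in the common limb. The alimentary limb showed no such direction, with 45.5% to 63.1% and 28% to 72%.

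In the unblocked fit, IDs that rose in the alimentary limb leaned higher as a group in glucotonic than in non-glucotonic OLE sections, though none passed singly. Of 654 such IDs tested there, 519 (79.4%) had a positive log2 change, against 49.1% of other IDs, with a median shift of 0.175 over the other IDs (camera adjusted p = 9.91e-20 over 12 tests, 0.016 with an estimated correlation). Set against no change instead of other IDs, they passed fry (adjusted p = 0.024). Of 500 fallen IDs, 108 (21.6%) had a positive change, a shift of -0.124 (camera adjusted p = 2.5e-08, but adjusted p = 0.295 with an estimated correlation). With the number as a block the risen IDs' shift was 0.163 and camera's p with an estimated correlation 0.0616. Against Sham_OLE the risen IDs were shifted by 0.237 in glucotonic sections (camera adjusted p = 1.08e-08, adjusted p = 0.092 with an estimated correlation) and by 0.0426 in non-glucotonic sections (camera adjusted p = 0.238). The 0.237 was 0.222 with the libraries of number 13 kept apart and 0.0967 with lane 7, which held every Sham_OLE library, as a covariate in that fit, and 2 of 35 splits gave a shift as large, the highest other 0.248, so chance cannot be excluded for it. The limb score was higher in the glucotonic section of all 4 numbers, by 0.123 (13), 0.388 (16), 0.666 (18) and 0.48 (19). The mean was 0.414 with an SD of 0.226 (exact paired permutation test, two-sided, p = 0.125, the smallest that 4 pairs can give). For number 13, the lane 4 pair gave -0.078 and the lane 7 pair 0.324. Its non-glucotonic libraries scored 0.277 (lane 4) and -0.124 (lane 7), and its glucotonic libraries 0.199 (lane 4) and 0.2 (lane 7). The titles of these non-glucotonic libraries also differ in the number that follows 13, while those of the glucotonic libraries share it. Lane and that title number therefore cannot be told apart here.

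Several explanations were weighed for this shift. A position of the sections nearer to jejunum or ileum, as the whole cause, is argued against by the 327 risen IDs whose segment difference had an unadjusted p above 0.2. They were shifted by 0.184 (camera with an estimated correlation, without the block, p = 0.00148). Small segment differences in these IDs cannot be excluded with 3 samples per segment. Their median exceeded every one of 10000 random lists matched on expression, but such lists treat IDs as independent, so this adds no support. Of the 35 splits of the 8 samples, 1 gave a shift as large as the real 0.175, and the highest of the others was 0.166, but these splits ignore the numbers; of the 8 that part every number, 1 reached 0.175 and the highest other was 0.154, and 8 are too few for a share under 0.05. Lane 7 held 1 library of each kind of section, both of number 13. Being balanced, it could hardly move the shift as a covariate (0.149, against 0.147 in that fit without the lane term), so the covariate is no test. Without its libraries the shift was still 0.146, which argues against lane 7 as the whole cause. Lanes 5 and 6 stay open. The 3 section pairs sequenced in the same lane came from 2 numbers. They differed in limb score by -0.078 and 0.324 (both 13) and 0.388 (16), a mean of 0.211 that counts number 13 by both pairs. The pairs of numbers 18 and 19, in different lanes, differed by a mean of 0.574. A candidate explanation, open beside lane and chance, is that glucotonic sections share part of the alimentary limb's response.

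For the alimentary limb against sham jejunum, the real split gave 1237 IDs and the highest of the other splits 0, and for the common limb 0 and 8; with 10 splits each, of which 1 and 10 reached the real count, no share under 0.05 can arise. For Glucotonic_OLE against Sham_OLE, 1 of 35 splits, the real one, gave as many as 5 IDs and the others 0. That is the smallest share that 35 splits can give, so neither chance nor lane 7 is excluded for that count. At an unadjusted p under 0.05, however, 2 other splits gave more IDs than the real 2380, 3874 and 3908, and both set numbers 13, 16 and 18 apart from 19, which points to a structure of the samples. The unblocked contrast of glucotonic with non-glucotonic sections gave 0 IDs, reached by all 35 splits, and the highest other split, which set a pair of numbers with both sections against the other pair, gave 10. Non-glucotonic sections against sham gave 0 IDs by edgeR, as did all 35 splits, beside 936 at an unadjusted p under 0.05 and 26 by DESeq2. With the number as a block, the real split gave 25 IDs and the highest of the other splits that part every number 0, 1 of 8 splits reaching the real count, which is too few for a share under 0.05.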
